A study of Mus musculus with 2 samples.

How the data were processed

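Nuclei were isolated from flash-frozen brain tissue of 1 library of 5xFAD mice and 1 library of 5xFAD mice with inducible loss of Clec7a in macrophages of the central nervous system, per the labels. Nuclear RNA was captured in droplets with 10x Genomics chemistry, so each count is a unique molecular identifier (UMI) and repeated reads of a molecule are counted once. The authors deposited raw counts per gene and barcode, with no barcode filter, made with Cell Ranger 8.0.0 per the file headers, and the genome build is mm10 per the submitters' processing notes. The annotation and the treatment of intronic reads are not given in the sources used here. The files hold 32285 genes and 1887785 barcodes for the 5xFAD library and 1919011 barcodes for the cKO library. Every measure that follows was computed from these counts.

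Barcodes with at least 1500 UMIs, at least 300 genes and at most 5% of UMIs from mitochondrially encoded genes were kept as nuclei. The rule, fixed before the data were examined, took the lowest of 500, 750, 1000, 1500 and 2000 UMIs at which at most 20000 barcodes passed in both libraries. This left 18191 and 14442 nuclei from 18939 and 15903 barcodes past the UMI and gene minimums. Doublets were scored per library with Scrublet as built into scanpy, with an expected rate of 8%. It marked 0 nuclei in the 5xFAD library, where it did not work, and 1996 nuclei (13.8%) in the cKO library. The fixed rule would have removed doublets from the cKO library alone, so, in a departure from that rule, doublets were kept in both libraries and their removal was run as an alternative. Counts were scaled to 10000 per nucleus and log-transformed, 3000 variable genes were chosen per library and combined, and 30 principal components and 15 neighbours were used for Leiden clustering at resolution 1.0, with both libraries together and no batch integration, giving 50 clusters.

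Clusters were named from marker genes fixed before the data were examined, by the mean log2 level of each class's markers over clusters, with excitatory and inhibitory neurons set apart by a ratio of at least 3 between their transmitter genes. A cluster stayed unnamed where fewer than 3 markers were detected in 10% of its nuclei, where another class led its top 10 genes, or, for clusters best matched by a class other than neurons, where markers of a second class were nearly as high. Neuron clusters were not held to that last rule. Thresholds for mixed clusters were set after the data were examined. Clusters with a median doublet score of at least 0.12 held 12.6% of kept nuclei in the 5xFAD library and 10.8% in the cKO library, and clusters with neuronal transcripts but no clear transmitter class, among them a cluster led by Prl and Gh, 6.19% and 2.76%. All unnamed nuclei together were 20.3% and 15.7%, and those that best matched microglia 2.61% and 2.82%. Shares of classes are over named nuclei, with exact Clopper-Pearson intervals.

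UMI counts were summed over the nuclei of each class and library and divided by their total to give CPM. The log2 ratio of CPM, cKO over 5xFAD, has an exact conditional binomial 95% interval, and levels have exact Poisson intervals. A library with fewer than 3 counts was set to 3 for ranks and medians. These intervals cover counting error only, and with 1 library per group there is no test and no p-value. Microglia-like sums held 1022763 and 1467118 UMIs, and excitatory neuron-like sums 66855712 and 83405890 UMIs. Genes were compared in the 8 classes with at least 200 nuclei in each library. Named genes were chosen by a rule fixed before the data were examined. They are Cx3cr1, the 12 highest and 12 lowest ratios in microglia-like nuclei among genes with at least 50 UMIs in the higher library, and the 5 highest and 5 lowest in each other class among genes with at least 100 UMIs. Their class CPM in that library had to be at least that of barcodes under 100 UMIs. Mitochondrially encoded, ribosomal protein and unnamed transcript genes, Xist, Tsix and the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were left out of these ranks. The 2 highest and 2 lowest members of each list and App, Thy1 and Apoe were added by name. A few genes that these rules name are not reported here. Members of the heat shock and mitochondrially encoded lists, and of lists in endothelial-like nuclei, are given as medians only.

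The 23 gene lists, fixed before the data were examined, are homeostatic microglia, DAM, CLEC7A-SYK-CARD9 signalling, other pattern recognition and lectin receptors, phagocytic receptors, lysosome, lipid handling, type I interferon response, MHC class I and II, inflammatory cytokines, complement, proliferation, reactive astrocyte, astrocyte homeostasis, disease-associated oligodendrocyte, myelin, neuronal immediate early, amyloid processing, synaptic, endothelial barrier and activation, heat shock and RNA quality, mitochondrially encoded, and sex genes. Some genes stand in more than 1 list, such as Apoe, Axl and H2-D1. A list's median is over members with at least 20 UMIs in the class, its counting interval comes from 2000 Poisson redraws of each count, and its percentile is among 10000 random lists of the same size matched on expression in 20 bins. A second percentile, among random lists matched on expression in 5 bins and genomic span in 10 bins, was added after the data were examined. Genomic spans and positions come from GENCODE vM21 on GRCm38, where 32235 of 32285 genes (99.8%) were found by identifier.

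Free RNA was taken from barcodes under 100 UMIs, which held 0.939% and 0.903% of all UMIs. Its share of a class is the median over markers of other classes of their level in the class relative to free RNA, which is an upper estimate. A second profile, from 93072 and 92128 barcodes with 200 to 399 UMIs, was added after the data were examined and gave 19.8% and 24.7% in microglia-like nuclei. For detection, each nucleus was thinned without replacement to 1000 UMIs. There were 17 alternatives fixed before the data were examined and 6 added later, covering calling, doublets, clustering, scaling, depth, free RNA, gene length and the list minimums. The EmptyDrops-like calls compared barcodes of at least 200 UMIs with the free-RNA profile by 10000 simulations at a false discovery rate of 0.01 and took classes from the nearest cluster centroid.

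The ratios, intervals, ranks and percentiles were tested on simulated counts drawn from the class means, with 200 genes changed. These are Poisson draws, the model that the intervals assume, with no variation between nuclei or animals. They hold no gene length trend and no difference in free RNA between the libraries, and the ranks were run without the free-RNA condition. They check the calculation and not how well the values hold in these libraries. For microglia-like nuclei, 95.8% of intervals over 7267 genes covered the simulated ratio, 90.0% of 2-fold changes had an interval apart from 0, and all 24 named genes were changed ones. For astrocyte-like nuclei, 95.6% of intervals over 9967 genes covered it and 98.0% of 2-fold changes were recovered. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 were used.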

Results

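Single-nucleus RNA sequencing was compared between the brains of mice with amyloid pathology and of mice that in addition had lost Clec7a from macrophages of the central nervous system. The 5xFAD mouse expresses human APP with familial Alzheimer's disease mutations under Thy1 regulatory sequence and forms amyloid plaques. In the conditional knockout (cKO) mice, an inducible Cre recombinase in the Cx3cr1 locus, which is active in microglia and other macrophages, removes loxP-flanked Clec7a. The 5xFAD library is labelled 5xFAD+/- Cx3cr1+/+ Clec7afl/fl, so it has the loxP-flanked gene and 2 unmodified Cx3cr1 alleles. The cKO genotype carries the Cre insertion in 1 Cx3cr1 allele. Loss of Clec7a therefore cannot be told apart from that insertion in any comparison below. Clec7a encodes CLEC7A (Dectin-1), a C-type lectin receptor that signals through the kinase SYK. The series title places the question in how microglial CLEC7A acts on amyloid plaque pathology. There were 2 libraries, 1 per group, so no difference below has a replicate check and no test across animals could be made. The number of animals behind each library is not given in the sources used here. The 5xFAD library held 186398956 UMIs and the cKO library 204506656 UMIs over all barcodes. After filtering, 18191 and 14442 nuclei were kept, with medians of 4020 and 8593 UMIs per nucleus. All intervals are 95% intervals that cover counting error only.

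Microglia-like, astrocyte-like and oligodendrocyte-like nuclei took larger shares of the named nuclei in the cKO library and striatal neurons a smaller share. Microglia-like nuclei, the resident macrophages of the brain, were 404 of 14498 named nuclei in the 5xFAD library (2.79%, 2.52 to 3.07) and 664 of 12176 in the cKO library (5.45%, 5.06 to 5.87; exact Clopper-Pearson intervals). The log2 ratio of these shares, cKO over 5xFAD, was 0.97 (0.79 to 1.15). Astrocyte-like nuclei made up 5.65% (5.28 to 6.04) and 9.85% (9.32 to 10.4), and myelin-forming oligodendrocyte-like nuclei 6.48% (6.09 to 6.90) and 13.6% (13.02 to 14.2). Oligodendrocyte precursor (OPC)-like nuclei were closer, at 2.36% (2.12 to 2.62) and 2.87% (2.58 to 3.18). Among neurons, excitatory neuron-like nuclei were 54.1% (53.2 to 54.9) and 47.4% (46.5 to 48.2), and inhibitory neuron-like nuclei 10.5% (9.97 to 10.97) and 8.16% (7.68 to 8.66). Striatal projection neuron-like nuclei, the principal cells of the striatum, were 12.2% (11.7 to 12.7) in the 5xFAD library and 3.18% (2.87 to 3.51) in the cKO library, a log2 ratio of -1.94 (-2.10 to -1.78). Hippocampal dentate granule neuron-like nuclei went the other way, with 1.45% (1.26 to 1.66) and 3.46% (3.14 to 3.80). Over non-neuronal nuclei alone, microglia-like nuclei took 13.2% (12.1 to 14.5) and 14.5% (13.5 to 15.5), and the direction turned for astrocyte-like nuclei, with 26.9% (25.3 to 28.5) and 26.2% (24.9 to 27.5), and for OPC-like nuclei, with 11.2% (10.1 to 12.4) and 7.62% (6.86 to 8.42). These shares depended on how nuclei were called: with the minimum doubled to 3000 UMIs the log2 ratio was -0.72 for microglia-like and -0.63 for oligodendrocyte-like nuclei and 0.018 for excitatory neuron-like nuclei. With calls against the free-RNA profile it was 0.37 for microglia-like, 0.61 for oligodendrocyte-like, 0.039 for astrocyte-like and -0.055 for OPC-like nuclei. Median depth differed between the libraries by class, with 4631 and 13571 UMIs in excitatory neuron-like nuclei against 2370 and 2033 UMIs in microglia-like nuclei.

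**Figure D1:**
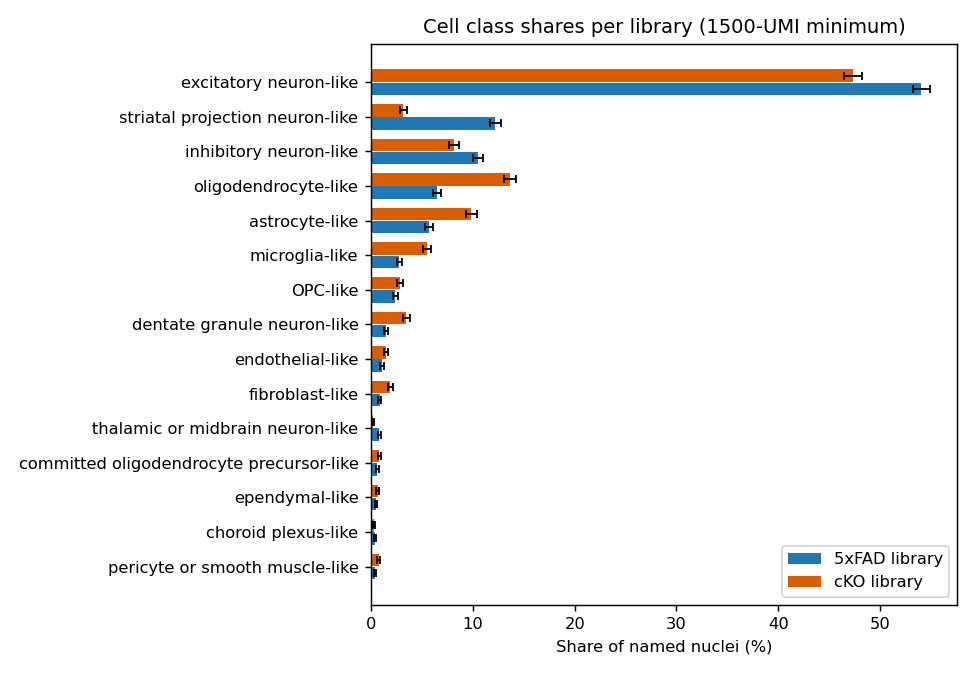
Share of named nuclei (%) in each cell class of the 5xFAD library (blue) and the cKO library (orange), with exact 95% binomial intervals that cover counting error only. Microglia-like nuclei were 2.79% and 5.45%, and striatal projection neuron-like nuclei 12.2% and 3.18%.

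The targeted gene, Clec7a, was not analysed here, so the genotype labels were not checked by it. Cx3cr1, the fractalkine receptor that carries the Cre insertion in the cKO genotype, was lower in the microglia-like nuclei of the cKO library. It had 625 UMIs, or 611 CPM (UMIs of the gene scaled by the class total; Poisson interval 564 to 661), in the 5xFAD library and 737 UMIs, or 502 CPM (467 to 540), in the cKO library. The log2 ratio was -0.28 (-0.44 to -0.13), with -0.46 at a minimum of 3000 UMIs and -0.10 with at most 1% mitochondrially encoded UMIs. A Cx3cr1 UMI was found in 68.6% (63.8 to 73.1) and 58.9% (55.0 to 62.7) of microglia-like nuclei, at the median depths of 2370 and 2033 UMIs given above. Excitatory neuron-like nuclei, which should lack the receptor, had 2.69% and 4.96% at medians of 4631 and 13571 UMIs, and barcodes under 100 UMIs had 18.3 and 19.0 CPM. Cx3cr1 (ENSMUSG00000052336) lies on chromosome 9, 119901616 to 120069879, on the minus strand of GRCm38 (mm10).

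In microglia-like nuclei, genes of the disease-associated microglia (DAM) programme and of the lysosome were higher in the cKO library, while the medians of the homeostatic programme and of the signalling genes downstream of CLEC7A lay near 0 over members that went both ways. The heat shock and RNA quality list was also higher in these nuclei, with a median log2 ratio of 0.41 (0.11 to 0.50), or 0.021 with the length trend removed. The DAM genes, which microglia around plaques express, had a median log2 ratio of 0.38 (0.26 to 0.51), with 26 of 38 measured members higher and 12 lower in the cKO library. Among these, Ch25h, which makes an oxysterol, had a log2 ratio of 1.02 (-0.0056 to 2.16) and the actin-capping gene Capg 0.93 (0.046 to 1.89). At the other end, Cd52 had -0.52 (-1.65 to 0.61) and Mamdc2 -1.08 (-1.48 to -0.68). Apoe, the main apolipoprotein of the brain and a DAM gene, had 471 CPM (430 to 515) in the 5xFAD library and 800 CPM (754 to 847) in the cKO library, a log2 ratio of 0.76 (0.61 to 0.92), with 762 and 976 CPM in barcodes under 100 UMIs. The lysosome list had a median of 0.40 (0.26 to 0.48), with 23 of 28 members higher. The protease gene Ctsl had a log2 ratio of 0.83 (0.47 to 1.21), the lysosomal membrane gene Cd68 0.75 (0.26 to 1.27), the proton pump subunit Atp6v1h -0.24 (-0.59 to 0.12) and the transcription factor Mitf -0.31 (-0.43 to -0.19). Homeostatic microglial genes had a median of 0.054 (-0.044 to 0.13), with 12 of 22 members higher, and its sign turned, to -0.29 at a minimum of 3000 UMIs and to -0.092 with the length trend removed. Its ends were Jun at 0.62 (-0.30 to 1.60) and Cst3, a secreted protease inhibitor, at 0.50 (0.38 to 0.62; -0.27 with the second free-RNA profile subtracted), against Mef2c at -0.28 (-0.36 to -0.20) and the lectin Siglech at -0.35 (-0.50 to -0.20). The CLEC7A-SYK-CARD9 signalling list had a median of -0.018 (-0.11 to 0.096), with 13 of 26 members higher. Within it, Bcl10 had 0.81 (0.17 to 1.49), the NADPH oxidase subunit Cybb 0.70 (-0.13 to 1.59), and the exchange factors Vav2 -0.49 (-0.80 to -0.17) and Vav3 -1.21 (-2.02 to -0.42), the last of which was higher in the cKO library, at 0.75, with 3000 UMIs as the minimum.

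Shorter genes had higher ratios than longer genes in every class compared. In microglia-like nuclei the median log2 ratio was 0.40 over the shortest 20% of genes and -0.11 over the longest 20%, with a Spearman correlation of -0.37 across 10612 genes, which are not independent replicates. Each list median is therefore set against 10000 random lists matched on expression and against 10000 matched on expression and gene length. The DAM median lay at percentile 100 of the first and 99.7 of the second kind, and the lysosome median at 100 of both. The homeostatic median lay at 97.2 and 9.56, and the CLEC7A-SYK-CARD9 median at 38.0 and 44.2. With the trend of ratio on length subtracted, the DAM median was 0.068 and the lysosome median 0.25. With nuclei thinned to 1000 UMIs the DAM median was 0.25, and at a minimum of 3000 UMIs the lysosome median was 0.23. The heat shock and RNA quality median lay at percentiles 99.75 and 86.4. Free RNA was estimated at up to 39.1% of the UMIs in microglia-like nuclei of the 5xFAD library and 45.6% in the cKO library.

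**Figure D2:**
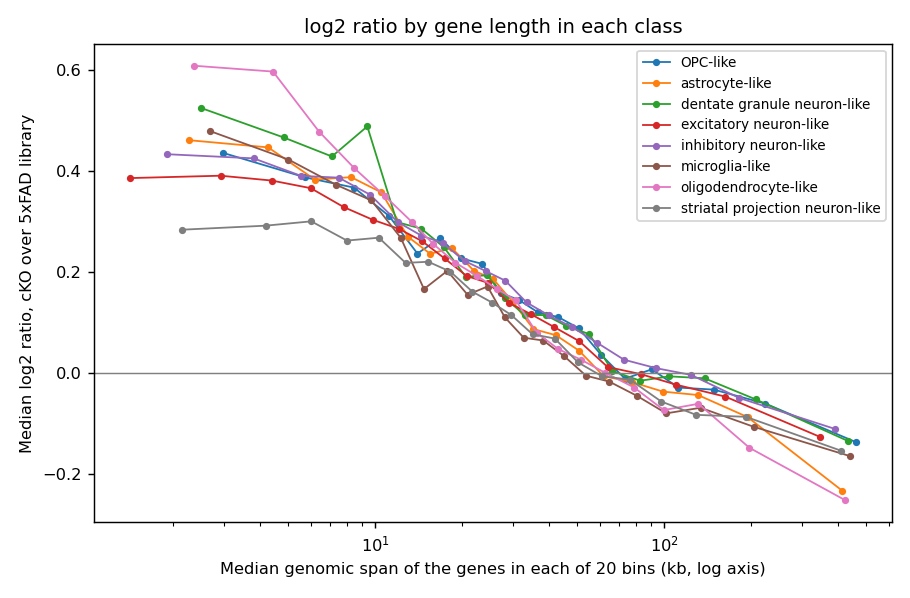
Median log2 ratio, cKO over 5xFAD library, against the median genomic span (kb, log axis) of the genes in each of 20 bins of length, for the 8 classes compared (lines). In microglia-like nuclei the shortest 20% of genes had a median of 0.40 and the longest 20% -0.11.

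Other microglial groups were mixed. Type I interferon response genes had a median log2 ratio of 0.43 (0.23 to 0.60), with 19 of 22 members higher in the cKO library, at percentiles 99.97 and 99.97 of the lists matched on expression and on expression and length, and of 0.095 with at most 1% mitochondrially encoded UMIs. Ifit3 had 1.67 (0.47 to 3.10) and Ifit2 1.22 (0.26 to 2.28), from 7 and 12 UMIs in the 5xFAD library, while Ifih1 had -0.23 (-0.71 to 0.27) and Xaf1 -0.32 (-0.87 to 0.23). Antigen presentation genes (MHC class I and II) had a median of 0.59 (0.33 to 0.93) with 10 of 11 members higher, at percentiles 99.7 and 96.1, and of 0.22 with the length trend removed. Psmb9, an immunoproteasome subunit, had 1.17 (0.25 to 2.19) and H2-D1 1.08 (0.65 to 1.54), against H2-DMa at 0.12 (-0.53 to 0.79) and Nlrc5 at -0.15 (-0.62 to 0.33). Complement genes had a median of 0.071 (-0.080 to 0.38) with 5 of 9 members higher, at percentiles 82.6 and 14.6 (-0.23 at a minimum of 3000 UMIs), and its highest members were the C1q subunits C1qa at 1.24 (0.98 to 1.51) and C1qc at 0.81 (0.57 to 1.06). The lowest were the integrin Itgb2 at -0.26 (-0.75 to 0.23) and Cr1l at -0.34 (-0.69 to 0.025).

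Phagocytic receptors had a median of 0.010 (-0.089 to 0.10) with 13 of 23 members higher, at percentiles 70.2 and 44.9. Msr1 had 0.87 (-0.36 to 2.26) and Axl 0.70 (0.32 to 1.09), against Dock2 at -0.25 (-0.34 to -0.16). Lipid handling genes had a median of 0.14 (0.0002 to 0.32) with 12 of 18 higher, at percentiles 84.3 and 74.6, with the sterol regulator Srebf1 at 1.31 (0.21 to 2.56) and Apobr at -0.34 (-1.43 to 0.76). Other pattern recognition and lectin receptors had a median of 0.42 (-0.086 to 0.58) with 7 of 13 higher, at percentiles 96.5 and 94.7 (-0.099 with members counted from 1 UMI), led by Clec4a2 at 1.25 (0.20 to 2.43) and the inflammasome sensor Nlrp3 at 0.64 (0.28 to 1.02). Its lowest members were Nod2 at -0.52 (-1.94 to 0.90) and Nod1 at -0.71 (-1.40 to -0.027). Inflammatory cytokine genes had a median of 0.22 (0.010 to 0.54) with 8 of 13 higher, at percentiles 70.1 and 32.1 (-0.016 with the length trend removed), from Ccl12 at 1.37 (0.13 to 2.82) and Il6 at 1.16 (-0.36 to 2.96) to Cxcl16 at -0.26 (-1.33 to 0.83) and Il18 at -0.35 (-0.76 to 0.058). Only 6 proliferation genes had enough UMIs, with a median of 0.53 (0.093 to 1.16) and 5 higher, at percentiles 87.8 and 92.5. That median was -0.008 with calls against the free-RNA profile and -0.078 with members counted from 1 UMI. These sums leave out the unnamed cluster led by the cell division genes Top2a and Knl1, with 55 and 116 nuclei. Its mean marker levels were nearly equal for OPC, at 4.15, and microglia, at 3.72. The list therefore does not measure how many microglia divided. Diaph3 had 1.68 (0.25 to 3.43), but -0.58 with those calls, Atad2 0.97 (0.39 to 1.59), Pola1 0.20 (-0.28 to 0.69) and Mcm3 -0.051 (-1.16 to 1.10).

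**Figure D3:**
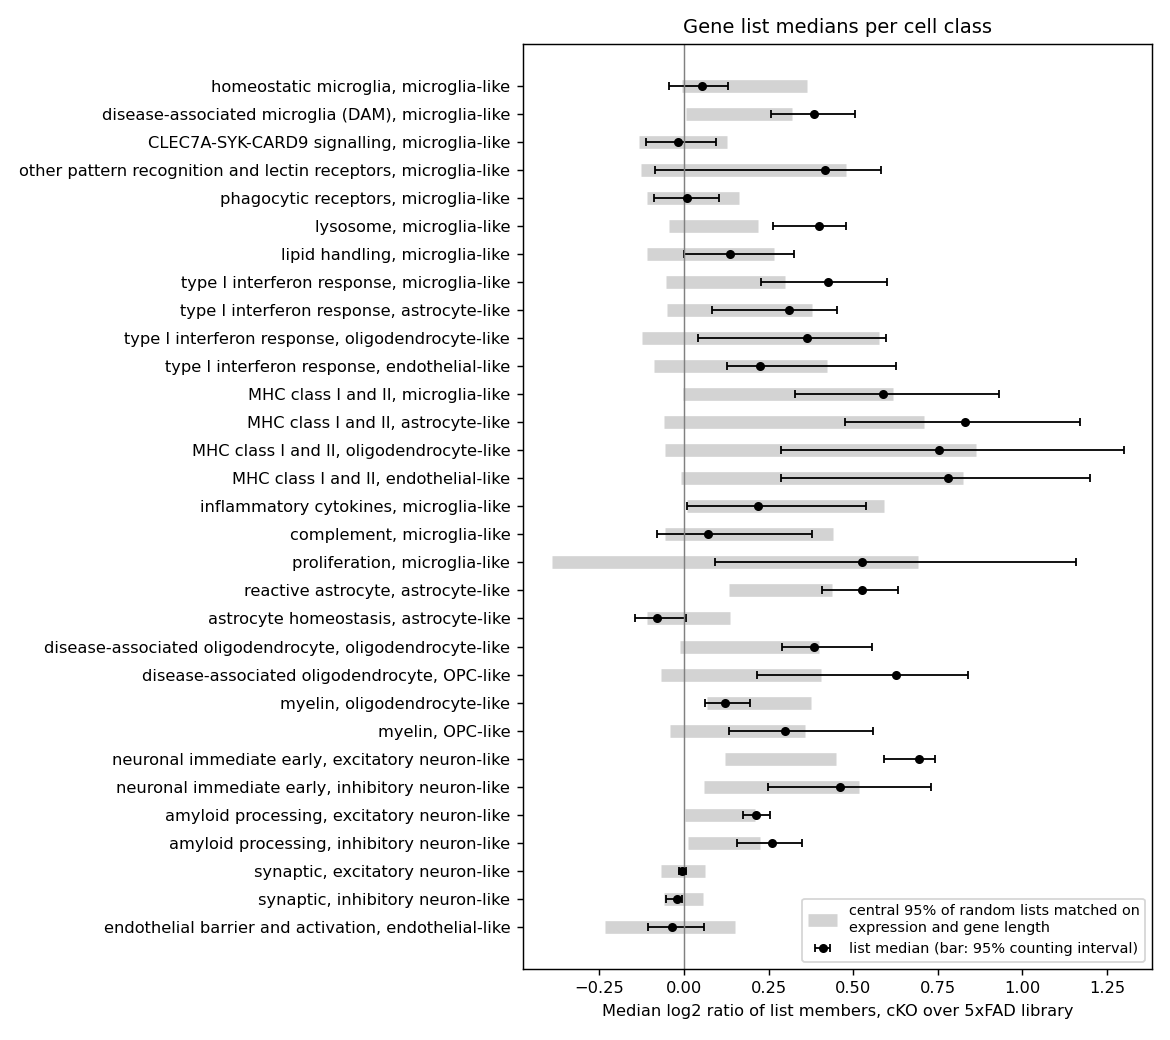
Median log2 ratio of the members of each gene list in its cell class, cKO over 5xFAD library (points, with 95% counting intervals), over the central 95% of random lists matched on expression and gene length (grey). The lysosome median of 0.40 lay above its band, and the CLEC7A-SYK-CARD9 median of -0.018 within it.

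Of single genes in microglia-like nuclei, C1qa, which encodes a chain of the complement recognition protein C1q, combined a high ratio with many counts. It had 155 UMIs (152 CPM, 129 to 177) in the 5xFAD library and 525 UMIs (358 CPM, 328 to 390) in the cKO library, and a UMI was found in 29.2% (24.8 to 33.9) and 46.2% (42.4 to 50.1) of these nuclei. Excitatory neuron-like nuclei had a C1qa UMI in 3.31% and 7.94%, and barcodes under 100 UMIs had 46.9 and 94.2 CPM. F13a1, a marker of macrophages at the borders of the brain, had a log2 ratio of 1.34 (0.80 to 1.9), from 36.2 to 91.3 CPM, but 0.20 with at most 1% mitochondrially encoded UMIs and 3.16 at a minimum of 3000 UMIs. The largest ratio was that of Atp13a5, a gene of pericytes, at 1.83 (0.88 to 2.91) from 11 and 56 UMIs, and its sign turned, to -0.47, when the called doublets of the cKO library were removed. Dnajc15, Rnf123, Cops7a, Tmem126a, Sf3a1, Rap2b, Nup54, Ncbp2 and Poglut1 had log2 ratios between 1.22 and 1.52 with at most 21 UMIs each in the 5xFAD library, and Rnf123 turned to -0.20 with at most 1% mitochondrially encoded UMIs. Which genes rank highest and lowest depended on the rule: of the 24 ranked genes, 1 (Atp13a5) stayed at 20 UMIs, 4 without the free-RNA condition and 16 with the second free-RNA profile in that condition. At the low end, Mamdc2 had 131 and 89 UMIs, a log2 ratio of -1.08. The protein kinase gene Prkg1 had -0.93 (-1.07 to -0.79), from 985 to 516 CPM, and the catenin gene Ctnna3 -0.89 (-1.03 to -0.76), from 950.4 to 511 CPM. Sp4, Sugct, Taf4, Ptpn4, Ston2, Usp35, Tmlhe, Zfyve1 and Zfp984 had log2 ratios between -1.03 and -0.79. In GRCm38, C1qa (ENSMUSG00000036887) spans 136895917 to 136898803 on chromosome 4 and F13a1 (ENSMUSG00000039109) spans 36867178 to 37050244 on chromosome 13. Mamdc2 (ENSMUSG00000033207) spans 23302609 to 23448442 and Prkg1 (ENSMUSG00000052920) spans 30564489 to 31765033, both on chromosome 19. Ctnna3 (ENSMUSG00000060843) spans 63430098 to 65003667 on chromosome 10, and all 5 are protein-coding. Mamdc2, Ston2 and Zfp984 were higher in the cKO library when nuclei needed 3000 UMIs, and Sugct when nuclei were thinned to 1000 UMIs.

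**Figure D4:**
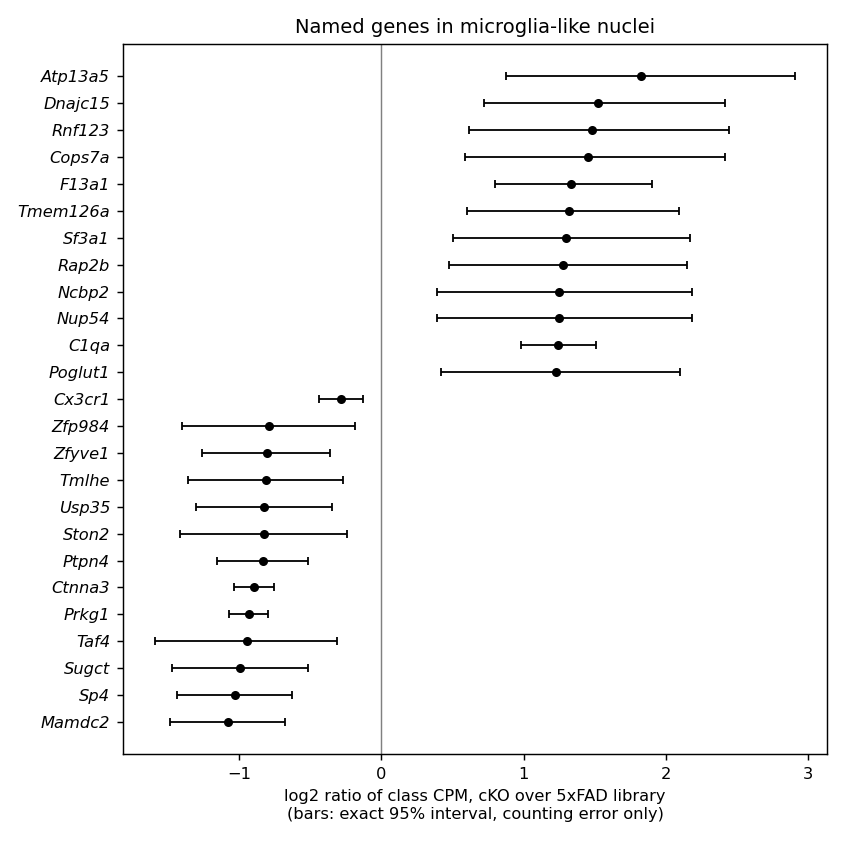
log2 ratio of class CPM, cKO over 5xFAD library, for Cx3cr1 and the 12 highest and 12 lowest genes in microglia-like nuclei (points), with exact 95% intervals that cover counting error only. C1qa, at 1.24, and Prkg1, at -0.93, had narrow intervals among them.

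At equal depth, DAM transcripts were found in more microglia-like nuclei of the cKO library, by 5.99 percentage points, with 1.84 points when the called doublets of the cKO library were removed and 10.3 points with at most 1% mitochondrially encoded UMIs. With every nucleus thinned to 1000 UMIs, and none left out for lack of depth, UMIs of at least 2 of the 38 DAM genes were found in 90.1% (86.8 to 92.8) of 404 nuclei and 96.1% (94.3 to 97.4) of 664 nuclei. UMIs of at least 3 were found in 80.7% (76.5 to 84.4) and 89.6% (87.0 to 91.8). Thinned to 500 UMIs, the shares lay closer, with overlapping intervals. They were 78.2% (73.9 to 82.1) and 83.1% (80.1 to 85.9) for at least 2, and 56.9% (51.9 to 61.8) and 63.6% (59.8 to 67.2) for at least 3. Without thinning the shares with at least 2 were 97.8% and 99.7%. Excitatory neuron-like nuclei, set beside them as a background, had at least 2 in 43.4% and 34.1% when thinned to 1000 UMIs. Their free RNA was estimated at up to 11.8% and 7.34% of UMIs, against 39.1% and 45.6% in microglia-like nuclei. They may therefore understate the background in microglia-like nuclei, and thinning evens out depth but not free RNA.

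Astrocyte-like nuclei of the cKO library had higher levels of reactive astrocyte genes and a median near 0 for homeostatic genes, which went both ways. The reactive list had a median log2 ratio of 0.53 (0.41 to 0.63), with 20 of 23 members higher, at percentiles 100 and 99.8 of lists matched on expression and on expression and length, and 0.24 with the length trend removed. Heat shock and RNA quality genes had 0.25 (0.078 to 0.41) in these nuclei, at percentiles 96.1 and 35.95, and -0.014 with the length trend removed. H2-D1, of MHC class I, had 1.55 (0.69 to 2.51) and the transcriptional regulator Id3 1.28 (0.97 to 1.60), against the matrix gene Tnc at -0.013 (-0.28 to 0.26) and the fatty acid-binding gene Fabp7 at -1.05 (-1.60 to -0.52). Astrocyte homeostasis genes had a median of -0.079 (-0.14 to 0.0048) with 8 of 18 higher, at percentiles 36.2 and 6.48. The sodium pump subunit Atp1b2 had 0.81 (0.66 to 0.95) and the gap junction gene Gja1 0.50 (0.38 to 0.62), against Gpc5 at -0.25 (-0.27 to -0.23) and Trpm3 at -0.52 (-0.55 to -0.49). By size, Coq10b had 1.81 (1.41 to 2.23), Tex11 1.54 (0.92 to 2.21), Fkbp5 1.51 (1.07 to 1.97), Zbtb16 1.45 (1.27 to 1.64) and the NF-kB inhibitor gene Nfkbia 1.31 (0.90 to 1.73). Crym, which encodes a thyroid hormone-binding protein, was lowest at -2.56 (-3.11 to -2.04), from 48.0 to 8.12 CPM, followed by Cdk5rap1 at -0.99, Spon1 at -0.97, Eepd1 at -0.90 and the clock gene Arntl at -0.87 (-1.08 to -0.66). The libraries differed in their share of striatal neurons, and the regions that astrocyte-like nuclei came from were not compared. A different mix of regions therefore cannot be told apart from these ratios. Apoe in astrocyte-like nuclei had a log2 ratio of 0.53 (0.43 to 0.62).

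In oligodendrocyte-like nuclei, genes of disease-associated oligodendrocytes were higher in the cKO library, with a median log2 ratio of 0.38 (0.29 to 0.56) and 15 of 18 members higher, at percentiles 99.6 and 96.5, the second within the central 95% of lists matched on expression and length. It was 0.21 at a minimum of 3000 UMIs, and heat shock and RNA quality genes had 0.41 (0.23 to 0.58) in the same nuclei, and -0.043 with the length trend removed. Serpina3n, a protease inhibitor, had 1.89 (0.49 to 3.63) from 5 UMIs in the 5xFAD library and H2-D1 1.72 (0.93 to 2.60), against Cdkn1a and Klk6 at -0.49 each, with intervals of -1.83 to 0.86 and -1.43 to 0.46. Myelin genes had a median of 0.12 (0.062 to 0.20) with 18 of 23 higher, at percentiles 99.2 and 13.4, and of -0.099 once the length trend was removed. Mal had 0.68 (0.57 to 0.79) and the lineage factor Olig1 0.57 (0.25 to 0.90; -0.045 at a minimum of 3000 UMIs), against Ugt8a at -0.23 (-0.31 to -0.15) and Olig2 at -0.46 (-1.03 to 0.11). The highest single genes were Zbtb16 at 1.46 (1.33 to 1.58), Zfp553 at 1.34, the lipid droplet gene Plin4 at 1.30 (0.77 to 1.85), complement C4b at 1.28 (0.92 to 1.67) and Hif3a at 1.20 (0.65 to 1.78). Eml1 at -0.95 (-1.08 to -0.83), Shroom3 at -0.86, Ctdspl at -0.84, and Sema5a and Piezo2 at -0.82 each were lowest.

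In OPC-like nuclei the disease-associated oligodendrocyte list had a median of 0.63 (0.21 to 0.84) with 10 of 13 higher, at percentiles 99.95 and 99.94, and of 0.18 with free RNA subtracted. H2-D1 had 1.13 (-0.012 to 2.37) and Ptgds 0.91 (0.56 to 1.27), against Sgk3 at -0.032 (-0.38 to 0.32). Myelin genes there had 0.30 (0.13 to 0.56) with 13 of 19 higher, at percentiles 97.9 and 93.0 (-0.19 with the called doublets of the cKO library removed), from Mal at 1.57 (0.86 to 2.34) and Mog at 1.40 (-0.024 to 3.05) to Mobp at -0.36 (-0.71 to -0.024; 0.16 with at most 1% mitochondrially encoded UMIs) and Fa2h at -0.49 (-0.89 to -0.083). Zbtb16 at 1.27 (0.96 to 1.59), Nnat and Srsf7 at 0.99 each, Olig1 at 0.97 and Afg1l at 0.93 were highest. Lypd6 at -1.01 (-1.41 to -0.62), Sdc2 at -0.87, Arhgef3 at -0.82, Lrrc28 at -0.75 and Ptpn14 at -0.69 were lowest.

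Excitatory neuron-like nuclei of the cKO library had higher levels of activity-induced immediate early genes and a median near 0 for synaptic genes that went both ways. Heat shock and RNA quality genes were also higher there, with a median of 0.50 (0.21 to 0.54) and 11 of 12 members higher, at percentiles 99.97 and 97.6, and of 0.12 with the length trend removed. The immediate early list had a median log2 ratio of 0.69 (0.59 to 0.74) with 18 of 20 members higher, at percentiles 100 and 100, from Ier2 at 1.42 (1.06 to 1.79) and Btg2 at 1.36 (1.19 to 1.52) to the scaffold gene Homer1 at -0.074 (-0.096 to -0.053) and the neurotrophin gene Bdnf at -0.14 (-0.22 to -0.059). With the length trend removed the median of the list was 0.40. In inhibitory neuron-like nuclei its median was 0.46 (0.25 to 0.73) with 15 of 19 higher, at percentiles 98.3 and 94.9 (0.095 with nuclei thinned to 1000 UMIs and 0.24 with the length trend removed), with Ier2 at 1.65 (0.60 to 2.84), Fos at 1.46 (0.69 to 2.30), Egr3 at -0.26 (-0.77 to 0.25) and Npas4 at -0.35 (-1.02 to 0.31). Synaptic genes had medians of -0.0061 (-0.015 to 0.0055) in excitatory and -0.021 (-0.052 to -0.0058) in inhibitory neuron-like nuclei, at percentiles 85.3 and 60.8 of lists matched on expression and 47.5 and 26.8 of lists matched on expression and length. In excitatory neuron-like nuclei 15 of 30 synaptic members were higher, from the vesicular glutamate transporter Slc17a7 at 0.90 (0.87 to 0.94) and Vamp2 at 0.48 (0.40 to 0.56) to Nrxn3 at -0.28 (-0.29 to -0.28) and Gabrb2 at -0.30 (-0.32 to -0.28). In inhibitory neuron-like nuclei 11 of 30 were higher, with Slc17a7 at 0.48 (-0.16 as a mean of nucleus CPM), Vamp2 at 0.39 (-0.042 with the length trend removed), the glutamate receptor gene Gria1 at -0.24 and Nlgn1 at -0.33.

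Genes of amyloid precursor processing had a median of 0.21 (0.17 to 0.25) in excitatory neuron-like nuclei, with 19 of 23 higher, at percentiles 98.5 and 97.6, and of 0.26 (0.16 to 0.35) in inhibitory neuron-like nuclei, with 20 of 23 higher, at percentiles 99.3 and 99.1. The gamma-secretase subunit Aph1a had 0.78 (0.64 to 0.91) in excitatory and 0.67 (0.35 to 1.0) in inhibitory neuron-like nuclei, and Psenen 0.74 (0.57 to 0.92) in excitatory ones. Itm2c had 0.64 (0.42 to 0.86) and Aph1c -0.12 (-0.48 to 0.25) in inhibitory ones. The protease gene Bace2 had -0.75 (-0.99 to -0.51) in excitatory and -1.13 (-1.94 to -0.37) in inhibitory neuron-like nuclei, where it turned to 0.19 with nuclei thinned to 1000 UMIs, and the amyloid-degrading enzyme gene Mme -0.83 (-1.25 to -0.42) in excitatory ones. The median over genes with at least 50 UMIs was itself 0.14 in excitatory and in inhibitory neuron-like, 0.11 in astrocyte-like and 0.055 in microglia-like nuclei, and relative to it the medians of amyloid processing genes were 0.072 and 0.12 in excitatory and inhibitory neuron-like nuclei. App had log2 ratios of 0.043 (0.023 to 0.063) in excitatory neuron-like nuclei, -0.097 relative to that median, and 0.045 (-0.0008 to 0.090) in inhibitory neuron-like nuclei, 0.29 (0.12 to 0.45) in microglia-like (-1.08 with free RNA subtracted) and 0.37 (0.23 to 0.50) in astrocyte-like nuclei. Thy1, whose regulatory sequence drives transgene expression, had 0.63 (0.59 to 0.67) in excitatory, 0.61 (0.49 to 0.72) in inhibitory, 0.72 (0.46 to 0.97) in microglia-like and 0.66 (0.48 to 0.85) in astrocyte-like nuclei. Barcodes under 100 UMIs had 977 and 1174 CPM of App and 542 and 864 CPM of Thy1, above the class level in each of these classes. Apoe had -0.21 (-0.26 to -0.15) in excitatory and -0.25 (-0.38 to -0.11) in inhibitory neuron-like nuclei, the latter 0.061 with at most 1% mitochondrially encoded UMIs.

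In excitatory neuron-like nuclei, the transcription factor genes Tfap2d, at -2.10 (-2.49 to -1.72), and Sim1, at -1.37 (-1.87 to -0.89; 0.17 with the called doublets of the cKO library removed), were among the lowest, with Spag16 at -1.74, Ndst4 at -1.34 (-1.40 to -1.27) and Samd3 at -1.27. A cluster of this class that held 592 nuclei of the 5xFAD library and 45 of the cKO library, or 7.55% and 0.78% of the class, differed most in size. Tfap2d and Ndst4 were among the top 10 genes of that cluster. Their lower class ratios therefore cannot be told apart from its smaller size in the cKO library. The highest were Nlrp6 at 1.60, Col6a4 at 1.53, Kdm6bos at 1.25, and Gpr141 and Gpr18 at 1.20 each, all below 4 CPM, and Gpr18 turned to -0.69 with nuclei thinned to 1000 UMIs. In inhibitory neuron-like nuclei, the neuropeptide genes Crh, at 1.55 (1.13 to 1.99), and Tac2, at 1.34 (0.80 to 1.9), were highest, followed by Tmem132cos at 1.22, Dlx2 at 1.20 and the vesicular GABA transporter Slc32a1 at 1.13 (0.94 to 1.33). Sfta3-ps at -2.25 (-2.74 to -1.78), Adgrg6 at -1.27, Colgalt2 at -1.14, Gpc3 at -1.13 and Nxph2 at -1.09 were lowest. Regions of origin were not compared for inhibitory neuron-like nuclei either, so a different mix of them cannot be told apart from these ratios. In striatal projection neuron-like nuclei, Impg1 at 1.57 (1.37 to 1.77), the clock gene Per2 at 1.46 (1.21 to 1.71), Mhrt at 1.29, Rassf8 at 1.06 and Coq10b at 1.02 were highest, and Tacr1 at -1.91, Adamts18 at -1.73, Tcerg1l at -1.54, Insyn2b at -1.51 (0.19 with nuclei thinned to 1000 UMIs) and Cdh4 at -1.49 lowest. In dentate granule neuron-like nuclei, Rnf25 at 1.42, Plk5 at 1.30, Hdac6 at 1.24, Gnl3 at 1.22 and Utp11 at 1.13 were highest, and Nhs at -2.01 (-2.48 to -1.55), Cdh13 at -1.16 (-1.28 to -1.03), Myo5b at -1.10, Lcorl at -0.94 and Trabd2b at -0.94 lowest.

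Outside microglia-like nuclei, antigen presentation genes had medians above 0 from few counts, and of the 3 classes measured the astrocyte-like median alone lay above both kinds of random lists at the main settings. Interferon medians lay within the central 95% of both kinds in all 3 classes. MHC class I and II genes had medians of 0.83 (0.48 to 1.17) in astrocyte-like, 0.75 (0.29 to 1.30) in oligodendrocyte-like and 0.78 (0.29 to 1.20) in endothelial-like nuclei, but the astrocyte-like median was 0.26 with nuclei thinned to 1000 UMIs, and the oligodendrocyte-like median turned to -0.24 once free RNA was subtracted. Their percentiles were 99.9, 98.0 and 99.7 among lists matched on expression and 99.6, 93.6 and 96.0 among lists matched on expression and length. B2m had 1.09 (0.60 to 1.60) in astrocyte-like nuclei and 1.21 (0.70 to 1.75) in oligodendrocyte-like nuclei, while barcodes under 100 UMIs had 60.0 and 80.7 CPM, more than either class. Tap2 and Tap1 had 0.19 and -0.58 in astrocyte-like nuclei, and Nlrc5 and H2-DMa had -0.020 and -0.13 in oligodendrocyte-like nuclei. Type I interferon genes had medians of 0.31 (0.084 to 0.45), 0.36 (0.041 to 0.60) and 0.23 (0.13 to 0.63) in these classes, at percentiles 86.9, 75.2 and 91.1 on expression and 91.3, 80.3 and 70.7 on expression and length. Parp14 and Ifit1 had 1.54 and 1.5 in astrocyte-like nuclei (Ifit1 -0.13 with nuclei thinned to 1000 UMIs), against Usp18 at -0.40 and Rsad2 at -0.72. In oligodendrocyte-like nuclei Bst2 had 1 UMI in the 5xFAD library and 20 in the cKO library, a log2 ratio of 3.84 (1.19 to 9.21), and Ifit3 had 1.51, against Rnf213 at -0.23 and Ifih1 at -0.77. Endothelial barrier and activation genes had a median of -0.035 (-0.10 to 0.059) in 157 and 179 endothelial-like nuclei, with 7 of 16 higher, at percentiles 67.5 and 53.7.

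Signs of RNA quality also differed. Heat shock and nuclear RNA genes had medians of 0.24 in OPC-like, 0.25 in astrocyte-like, 0.26 in striatal, 0.37 in inhibitory, 0.41 in microglia-like, 0.41 in oligodendrocyte-like, 0.50 in excitatory and 0.56 in dentate granule neuron-like nuclei, with -0.14 in OPC-like nuclei as a mean of nucleus CPM. With the length trend removed they were -0.10 in OPC-like, -0.014 in astrocyte-like, -0.040 in striatal and -0.043 in oligodendrocyte-like nuclei, 0.021 in microglia-like and 0.12 in excitatory neuron-like nuclei. In dentate granule neuron-like nuclei thinned to 1000 UMIs the median was -0.19. Mitochondrially encoded genes were lower in the cKO library in excitatory (-0.34), inhibitory (-0.39) and striatal (-0.30) neuron-like nuclei, but with free RNA subtracted the excitatory and inhibitory medians were 1.16 and 0.41, and the striatal one was 0.13 with the second free-RNA profile subtracted. They were higher in astrocyte-like (0.21, and -0.068 as a mean of nucleus CPM), microglia-like (0.19, and -0.28 with the second free-RNA profile subtracted) and oligodendrocyte-like (0.34) nuclei, with 0.0008 in OPC-like and 0.052 in dentate granule neuron-like nuclei. Xist, the RNA of the inactive X chromosome, had 801 CPM in the 5xFAD and 976 CPM in the cKO library, and Tsix 20.4 and 29.9 CPM. The Y-linked genes Ddx3y, Uty and Kdm5d had 7, 7 and 5 UMIs in the 5xFAD library and 6, 7 and 5 in the cKO library, and Eif2s3y had 0 UMIs in both, which allows up to 0.0233 and 0.0214 CPM.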

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

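The signals below were flagged because they had more counts than the limit for a count of 0. They lie in nuclei that no gene comparison at the main settings used, or in the barcodes of the second free-RNA profile. Those barcodes were also candidates in the EmptyDrops-like calls. The signals were chosen after they were seen, so passing that limit tests nothing. A cluster led by the pituitary hormone genes Prl and Gh, which stayed unnamed, held 282 nuclei of the 5xFAD library and 67 of the cKO library at Leiden resolution 1.0. The cluster led by these genes held 156 and 7 nuclei at resolution 0.5, and 164 and 13 at resolution 2.0. In low-count barcodes of the 5xFAD library, those of the second free-RNA profile, Prl had 195 CPM and Gh 234 CPM, against 0.206 and 0.034 CPM, from 6 and 1 UMIs, in the cKO library, where Gh was under that limit and not flagged. Prl (ENSMUSG00000021342) lies on chromosome 13, 27057570 to 27065205, and Gh (ENSMUSG00000020713) on chromosome 11, 106300271 to 106301865. A cluster led by the cell division genes Top2a and Knl1 held 55 nuclei of the 5xFAD library and 116 of the cKO library.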

How the results depend on the processing

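Of the 6 alternatives chosen after the data were examined, the removal of the top 8% of doublet scores, the length trend, the second free-RNA profile and the minimum of 1000 UMIs appear here with a value. Over all alternatives, the DAM median in microglia-like nuclei ranged from 0.068 to 0.55, the lysosome median from 0.23 to 0.46, the reactive astrocyte median from 0.24 to 0.78, the immediate early median in excitatory neuron-like nuclei from 0.40 to 0.75 and the log2 ratio of Cx3cr1 from -0.46 to -0.10, all without a change of sign. Leiden resolution 2.0 and a total without mitochondrially encoded genes left the gene ratios, list medians, class shares and DAM detection recomputed under them within their counting intervals. Of the recomputed values of main results, 120 stayed within their counting interval, 28 moved beyond it and 1 changed sign from a main interval that excluded 0. Changes of sign from an interval that included 0, such as those of the homeostatic median, are counted among the 28. Of those of single genes, other lists and other shares, 3269 stayed within their interval and 437 moved beyond it, in the same direction or from an interval that included 0. Another 63 changed sign from an interval that excluded 0. Gene values in microglia-like nuclei rest on 1022763 and 1467118 UMIs, which limits them to abundant transcripts. In all cases below the cause was not tested. Class names stand for the nuclei of that class, values are log2 ratios or list medians unless stated, and shares are log2 ratios of shares.

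With the UMI minimum doubled, the number of nuclei kept in the 5xFAD library was 12039. The log2 ratio of excitatory neuron-like share was then 0.018, the microglia share -0.72 and the oligodendrocyte share -0.63. In microglia Mamdc2 was 0.24, Ston2 0.085, Zfp984 0.20, Vav3 0.75, Cx3cr1 -0.46, the homeostatic median -0.29 and the lysosome median 0.23. Olig1 in oligodendrocytes was -0.045, the reactive astrocyte median 0.69 and the disease-associated oligodendrocyte median 0.21. With at most 1% of UMIs from mitochondrially encoded genes, 11604 nuclei were kept in the 5xFAD library, the excitatory neuron share was 0.0091 and the microglia share 0.59. Cx3cr1 was -0.10, Rnf123 -0.20, Zfp984 0.18 and the DAM median 0.55 in microglia, Apoe 0.061 in inhibitory neurons and Mobp 0.16 in OPCs. The difference between libraries in microglia with at least 2 DAM genes, 5.99 percentage points, was then 10.3 points.

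With EmptyDrops-like calls the OPC share was -0.055 and the microglia share 0.37, with Diaph3 at -0.58, the proliferation median at -0.008 and the mitochondrial median at -0.080 in microglia and -0.047 in astrocytes. Removal of the called doublets gave an OPC share of -0.035, Sim1 at 0.17 in excitatory neurons, Atp13a5 at -0.47 in microglia, Slc17a7 at -0.55 in inhibitory neurons, a myelin median of -0.19 in OPCs and a DAM detection difference of 1.84 points. Removal of the top 8% of doublet scores gave Slc17a7 at -0.17 in inhibitory neurons. At Leiden resolution 0.5, Sim1 was 0.024 in excitatory neurons. Among non-neuronal nuclei only, the OPC share was -0.56, the astrocyte share -0.038 and the microglia share 0.13. A minimum of 1000 UMIs gave an OPC share of -0.061.

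Centred on the median gene, App was -0.097 in excitatory neurons, the disease-associated oligodendrocyte median 0.27 and the immediate early median 0.55. As a mean of nucleus CPM, Slc17a7 was -0.16 in inhibitory neurons, the heat shock median -0.14 in OPCs and the mitochondrial median -0.068 in astrocytes. Thinned to 1000 UMIs, Gpr18 was -0.69 and App -0.014 in excitatory neurons, Sugct 0.091 in microglia, Insyn2b 0.19 in striatal neurons, Ifit1 -0.13 in astrocytes, and Bace2 0.19 and Slc17a7 -0.063 in inhibitory neurons. The thinned heat shock medians were -0.075 in OPCs and -0.19 in dentate granule neurons, the mitochondrial median -0.11 in astrocytes, the DAM median 0.25, the reactive astrocyte median 0.35 and the immediate early median 0.53.

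With free RNA subtracted, App was -1.08 in microglia, the MHC median -0.24 in oligodendrocytes, the synaptic median 0.017 in inhibitory neurons, and the mitochondrial medians 1.16 in excitatory and 0.41 in inhibitory neurons. The reactive astrocyte median was 0.78 and the immediate early median 0.75. With the second free-RNA profile, App was -0.68 and Cst3 -0.27 in microglia, and the MHC median -0.13 in oligodendrocytes. The mitochondrial medians were 1.94 in excitatory, 1.41 in inhibitory and 0.13 in striatal neurons and -0.28 in microglia, the reactive astrocyte median 0.74 and the disease-associated oligodendrocyte median 0.26. With the length trend removed, Olig1 was -0.020 in oligodendrocytes, Vamp2 -0.042 in inhibitory neurons, the cytokine median -0.016 in microglia and the myelin median -0.099 in oligodendrocytes. The heat shock medians were -0.10 in OPCs, -0.014 in astrocytes, -0.043 in oligodendrocytes and -0.040 in striatal neurons, the homeostatic median -0.092, the DAM median 0.068, the lysosome median 0.25, the reactive astrocyte median 0.24 and the immediate early median 0.40. With list members counted from 1 UMI, the MHC median was -0.13 in oligodendrocytes and the proliferation median -0.078 in microglia.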

Other observations

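The lists of clock and glucocorticoid-responsive genes, and the tests of all 3 patterns weighed here, were chosen after the ratios had been seen. The bounds of each test were set before its value was known, with exceptions. The microglia-like medians over shared members and the length test over unseen members were added after a test had been seen. The length tests of the DAM and lysosome lists set the uncorrected medians against matched lists, whereas the written bound named the length-corrected ones. Genes of the circadian clock differed between the libraries in most classes. Clock genes that peak with Per2 had medians of 0.83 in excitatory, 0.64 in inhibitory and 0.69 in striatal projection neuron-like nuclei and 0.76 in astrocyte-like nuclei, 0.59 in oligodendrocyte-like and 0.57 in microglia-like nuclei. They were lower in OPC-like nuclei, with 0.33, and in dentate granule neuron-like nuclei, with 0.40, where Npas2, with 0.25 (-0.053 to 0.57), and Clock, with 0.22 (-0.0048 to 0.45), of the opposite phase were not lower. In excitatory neuron-like nuclei Ciart had a log2 ratio of 1.92 (1.73 to 2.12), Dbp 1.47 (1.31 to 1.64) and Per2 1.01 (0.93 to 1.09), while Arntl, which peaks in the opposite phase, had -0.39 (-0.44 to -0.35) and Npas2 -0.21 (-0.24 to -0.18). In astrocyte-like nuclei Ciart had 2.21 (1.49 to 3.02) and Arntl -0.87 (-1.08 to -0.66). Genes induced by glucocorticoids, such as Fkbp5, Zbtb16 and Hif3a, had list medians of 0.68 (0.53 to 0.94) over 17 members in oligodendrocyte-like nuclei and 0.67 (0.44 to 0.77) in astrocyte-like nuclei. The median was 0.51 (0.25 to 0.68) in microglia-like and 0.14 (0.0040 to 0.63) in OPC-like nuclei. Among neurons it was 0.40 (0.28 to 0.50) in excitatory, 0.35 (0.15 to 0.57) in inhibitory and 0.42 (0.16 to 0.74) in dentate granule neuron-like nuclei. In striatal projection neuron-like nuclei it was 0.19 (-0.15 to 0.31). Per2 spans 91415982 to 91459324 on chromosome 1, Arntl 113207465 to 113314126 on chromosome 7 and Zbtb16 48654297 to 48836222 on chromosome 9.

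The clock pattern may come from brains taken at different times of day. Over unseen members, genes that peak with Per2 had a higher median than the opposite phase in 7 of 8 classes, beyond counting error. The exception was dentate granule neuron-like nuclei. That difference was not matched on gene length, so the length trend may add to it. Against lists matched on expression and length, the unseen Per2-phase median lay above the band in astrocyte-like, oligodendrocyte-like, excitatory, inhibitory and striatal neuron-like nuclei. It lay within the band in OPC-like, microglia-like and dentate granule neuron-like nuclei, at percentiles 38.32, 95.55 and 89.61. The unseen opposite-phase median lay below its band in OPC-like nuclei alone. Whether a glucocorticoid state was shared by all cells cannot be decided. Members not seen beforehand stood above lists matched on expression and length in 1 of 8 classes, microglia-like nuclei. All members together also did so in astrocyte-like, oligodendrocyte-like and excitatory neuron-like nuclei. The full list holds members picked for their ratios, and the unseen set leaves those members out, so neither count settles it. Gene length and the glucocorticoid-responsive genes cannot be told apart in oligodendrocyte-like nuclei: with the trend removed the median was 0.38 (0.19 to 0.64), but over a list with members picked for their ratios. Over the 11 unseen members it was 0.20 (0.027 to 0.33), and before that removal they lay at percentile 94.0 of matched lists. Genotype and time of collection stay open, since each library is its own group.

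The higher DAM and lysosome medians in microglia-like nuclei may in part follow the gene length trend. With that trend removed the lysosome median stayed at 0.25 (0.11 to 0.30), which argues against length as its whole cause, whereas the DAM median was 0.068 (-0.020 to 0.26) although it lay above matched lists before, so length and the DAM programme cannot be told apart. Free RNA is argued against for DAM, whose median was 0.36 (0.26 to 0.56) over 37 members after the second free-RNA profile was subtracted. Whether the same genes shifted in every class stayed open: DAM medians were 0.021 over 9 members in astrocyte-like and -0.37 over 4 in oligodendrocyte-like nuclei, and lysosome medians 0.069 and 0.11 over 5 each. Over those members the microglia-like medians were -0.31 and -0.34 for DAM and -0.14 and 0.020 for lysosome, so they did not carry the pattern, and a genotype effect stays untested.

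The lower striatal projection neuron-like share in the cKO library may come from a different piece of brain in each library. Striatal markers were also lower in the barcodes of the second free-RNA profile, with a median log2 ratio of -0.97 (-1.02 to -0.92) over 10 markers, such as Pde10a at -1.10 and Adora2a at -1.42. A loss of these neurons would lower the same markers in free RNA, so these markers cannot separate a loss from a different piece. In the same barcodes, the pituitary gene Prl had 195 CPM in the 5xFAD library and 0.206 CPM in the cKO library. Gh had 234 and 0.034 CPM. A loss of striatal neurons would not account for that difference. Thalamic or midbrain neuron-like nuclei, 116 and 25, also had a lower share, at a log2 ratio of -1.96 (-2.65 to -1.33). Dentate granule neuron-like nuclei had a higher one, at 1.26. These values go with a different piece but do not exclude a loss. A UMI minimum at unequal depth is argued against as the whole cause, since with 3000 UMIs the log2 ratio among named neurons was -1.42 (-1.60 to -1.25), against -1.60 at the main minimum. A loss of striatal projection neurons with genotype was not tested and stays open.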
